A study of Mus musculus with 8 samples.

How the data were processed

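Goblet cells were sorted from intestinal epithelium of C57Bl/6 mice as CD45-negative, CD24-negative, cytokeratin 18-positive and UEA-I-binding cells, after release in buffer with 0.05% EDTA at 37 degrees C for 15 minutes, per the labels. RNA was extracted on columns, and biotinylated cRNA was hybridised to an Illumina mouse array, per the labels. The 8 samples fall into 2 groups, 4 from small intestine and 4 from colon. The scanner software, its version and the genome build were not given in the sources used here.

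The deposited table of signals holds, for each of 25697 probes and 8 arrays, the mean intensity on a linear scale, neither background-subtracted nor scaled, and a detection p-value, per the file headers and the values. Lowest signals were 96.7 to 113, and no value was negative. The steps of the deposited detection p-values correspond to 798 negative control probes. The array means of the signal ran from 386 to 558, and 12447 to 13922 probes per array were above background (detection p below 0.05). In 1 cell of the signal table, the probe of Zswim4 on colon array 3, the text was corrupted and not a number. It was restored from the straight line that links that array's deposited processed values to its signals. A further deposited table holds the authors' processed values, in intensity units and linear, with negative values. Each of its columns matched its own array's signals as an exact straight line, with a subtraction of 141 to 163 units and a scaling of every array to a mean of 293. Its column medians ran from 22.5 to 32.6. How the authors chose the subtraction was not given in the sources used here. That table served as an alternative, with values under 16 set to 16 before the log2 step.

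Background was corrected from the detection p-values with normexp and an offset of 16, followed by quantile normalization and log2, with neqc of limma 3.58.1 in R 4.3.3. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures. Gene names came from the platform's annotation, updated through the Entrez identifier for 23962 probes and through the accession for 9, against a mouse RefSeq gene table that was used for names only. The platform's name was kept for 7 probes. In all, 23978 probes carried 1 gene symbol, 0 several, and 1719 none, covering 16590 genes. No coordinates are given, since no build was named.

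Probes were tested where the detection p was below 0.05 on at least 4 of the 8 arrays, whichever these were. That left 13618 probes, or 53.0%, of which 817 had no gene name. A linear model per probe with empirical Bayes variances (lmFit and eBayes) compared colon with small intestine, two-sided, with Benjamini-Hochberg adjustment at 0.05. Each gene was represented by its tested probe with the highest mean over all arrays. Where a probe was above background on no array of a group, a bound was computed: the mean of the brighter group against the mean, per array, of the higher of the lowest normalized value among probes above background and the probe's own value. These lowest values were 5.28 to 5.61 log2. A fold measured near that floor understates the true one. Values are quantile-normalized, so levels are compared between arrays for 1 probe, not between probes.

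The following were set before the data were examined: the groups, the test, the 36 gene lists, all alternatives not named below as later additions, and the rule for the genes to be named. Named genes were the 13 highest in each segment by fold change among called genes above background on all 4 arrays of the higher segment with no overlap of values. To these were added up to 2 members with the largest rise and 2 with the largest fall from each list, and 21 genes named beforehand, of which 16 had a named probe. Muc2, Tlr5, Tlr9 and Car1 were among those with none and were not analysed here. Together these made 121 genes. Lists with at least 5 tested members were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. The lists covered sort markers, goblet cell products, enterocytes, bile acid handling, colonocytes, gut position factors, Paneth, enteroendocrine, tuft and stem cells, proliferation, immune and stromal cells, and pathways. Single values per array were compared by exact permutation over the 70 splits of the arrays.

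The model was tested on simulated arrays built from the real values, of which 16945 passed the filter, with 100 probes changed 2-fold and 100 changed 4-fold. Of the probes changed 2-fold, 26 of 100 were recovered, and of those changed 4-fold, 94 of 100. Of 128 calls, 8 were false. Small changes were therefore often missed at 4 arrays per group in this simulation. The real data held a far larger share of called probes, 2919 of 13618 tested, which makes the adjusted threshold less strict. The changed probes were drawn only from brighter tested probes, the largest spreads were capped, and noise was independent between probes. The recovery in the real data, above all for dim or widely spread probes, may thus differ and was not measured.

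The alternatives were other background corrections and offsets, other scalings between arrays, other filters on dim probes, the authors' processed values, array weights, a variance prior with an intensity trend, the replicate number as a block, the mean of all probes per gene, and the omission of each array in turn. The omissions were first run with the filter on dim probes re-applied to the arrays left. After these gave larger losses of calls, the same probes were tested instead, since a new filter changes a second choice and drops probes above background in 1 segment only. Both versions are reported, and the counts of alternatives include both. The slide of each array was not given in the sources used here, so slide was not used as a block. Leaving out colon replicates 1 and 4 together, and small-intestinal replicates 1 and 2 together, was chosen after the data were seen.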

Results

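Goblet cells, the mucus-secreting cells of the intestinal epithelium, were compared between the small intestine and the colon of C57Bl/6 mice. Epithelium was released with EDTA, and cells lacking CD45 and CD24 but carrying cytokeratin 18 and binding the lectin UEA-I were taken by flow cytometry. Their RNA was hybridised to an Illumina expression array. There were 4 samples from small intestine and 4 from colon, 1 array each. The labels do not say whether each sample came from a separate animal or pool of animals, so p-values measure the spread between these samples, which may be technical. The mean deposited signal was 472 ± 77.6 on the small-intestinal arrays and 432 ± 46.5 on the colon arrays (SD, n = 4 each), a difference within the spread (exact permutation test, two-sided, p = 0.371). Of 25697 probes, 13376 ± 637 per array were above background in small intestine and 12936 ± 387 in colon (exact permutation test, two-sided, p = 0.286, where 0.0286 is the smallest p possible). The number of arrays, 4 per group, limits the precision of every value.

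The question the design poses is how the transcript content of goblet cells differs between the gut segments. Beside secreting mucus, goblet cells are known to respond to microbial products and to pass luminal antigen, and gene lists for both were included. All fold changes below are colon minus small intestine on the log2 scale, so a positive value means higher in colon. Adjusted p-values are from limma with Benjamini-Hochberg correction unless another test is named. For a gene not above background on any array of a group, only a lower bound on the fold is given. Where a group was above background on some of its arrays only, the fold is measured near the floor and understates the true one.

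Goblet cell transcripts were above background in the sorted cells of both segments. Tff3, a trefoil peptide of the mucus, stood at 12.58 ± 0.07 log2 in small intestine and 12.27 ± 0.02 in colon (SD, n = 4 each; adjusted p = 0.202). Tff3 passed under 3 of 34 alternatives (adjusted p from 0.0295 to 0.465 over all of them), namely no background correction, no filter on dim probes and a variance prior with an intensity trend. Clca1, a secreted metalloprotease of mucus, stood at 12.46 ± 0.21 and 12.79 ± 0.18 (adjusted p = 0.243). Krt18, the cytokeratin of the sort, stood at 10.93 ± 0.28 and 11.26 ± 0.11 (adjusted p = 0.272). Spdef, a transcription factor of goblet cell maturation, was higher in colon, at 8.39 ± 0.29 against 6.84 ± 0.13 (log2 fold change 1.54, SE 0.20, adjusted p = 0.000214). Of the negative sort markers, Cd24a was above background on all 8 arrays and slightly higher in colon (log2 fold change 0.68, SE 0.22, adjusted p = 0.0458). The call for Cd24a was lost under 22 of 34 alternatives (adjusted p from 0.0109 to 0.294), among them the omission of any single array but small-intestinal replicate 1 and colon replicate 1. Ptprc, which encodes CD45, was also above background on all 8 arrays and was higher in small intestine, at 7.24 ± 0.41 against 6.25 ± 0.38 in colon (adjusted p = 0.0196). The call for Ptprc was lost under 8 of 34 alternatives (adjusted p from 0.00173 to 0.0649), among them without colon replicate 2 (0.0526). Fut2, a fucosyltransferase that makes the sugar UEA-I binds, was higher in colon by 5.09 (SE 0.22, adjusted p = 1.08e-07) and was above background on 1 of 4 small-intestinal arrays. No probe for Muc2 was named, and that gene was not analysed here.

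Goblet cells of the colon and the small intestine differed at 21.4% of the probes tested. Of 13618 probes above background on at least 4 arrays, 1580 were higher in colon and 1339 higher in small intestine, together 2919. By gene, with the brightest probe standing for each of 9080 genes, 1189 were higher in colon and 844 in small intestine. A measured change of at least 2-fold was found for 1397 genes, 799 of them higher in colon and 598 higher in small intestine. By measured fold, 41 genes in colon and 59 in small intestine were at least 16-fold higher. Such counts, here and below, include genes above background on no array of a segment, for which only a lower bound holds. That bound can lie below the threshold. For Hoxa11, the measured fold was 18.9 and the bound 13.5. For Tagln, these were 2.47 and 1.85. The counts were not repeated with the bounds. The 4 and 4 values did not overlap for 2377 genes, or 26.2% of those tested, where chance gives 2.86%. Of the called genes, 139 were above background on no small-intestinal array and 110 on no colon array. Another tested probe existed for 526 called genes and had the opposite sign for 40 of them. Segment also led the variation between arrays: the first principal component held 64.1% of the variance and parted the segments, and correlations between segments (0.762 to 0.880) lay below those within small intestine (0.923 to 0.982) and within colon (0.928 to 0.964). Without scaling between arrays, 744 probes were higher in colon and 1051 in small intestine, 41.4% of calls in colon against 54.1% with quantile normalization, and the median fold change of all genes moved from 0.07 to -0.14. With colon replicates 1 and 4 both left out, which held more of most Paneth cell transcripts as described below, 938 probes were higher in colon and 805 in small intestine, and 1191 genes differed at least 2-fold. With the filter on dim probes also re-applied to the arrays left, these were 657, 757 and 980. Re-applied after the omission of 1 array, the filter left 1044 probes higher in colon without colon replicate 4, and 777 and 798 higher in small intestine without small-intestinal replicates 3 and 4.

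**Figure D1:**
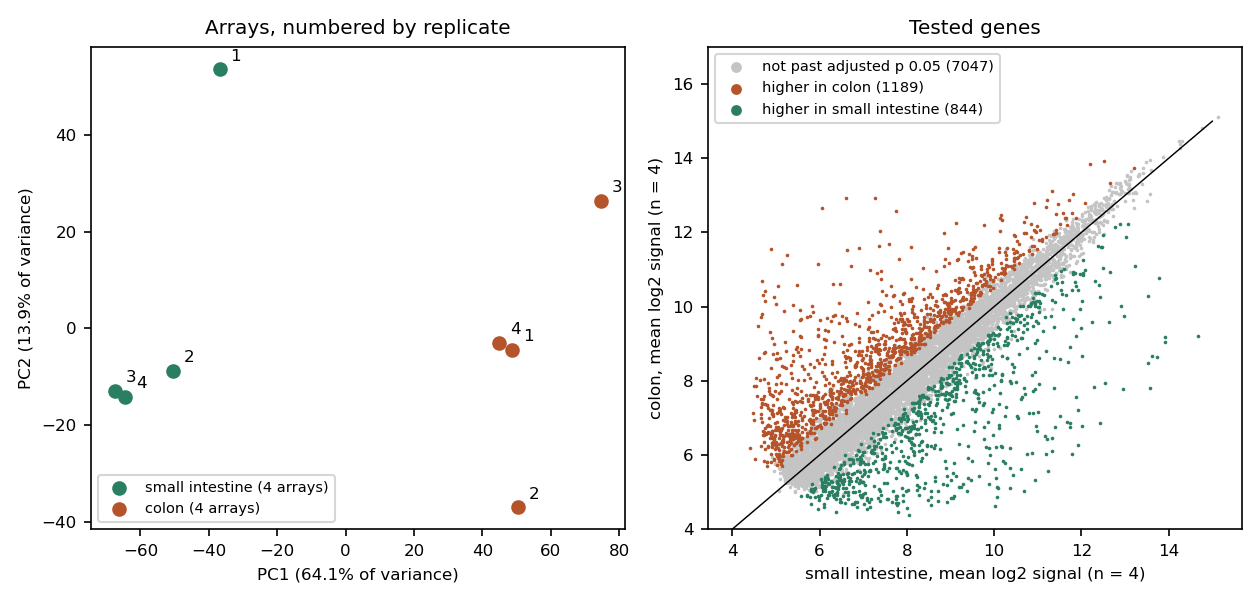
Left, the 8 arrays on the first and second principal components (percent of variance on each axis), numbered by replicate and coloured by segment: the segments part along the first component, and small-intestinal replicate 1 lies apart on the second, at 53.7. Right, mean normalized log2 signal of each of 9080 tested genes in small intestine (x) and colon (y), n = 4 each, with the 1189 genes higher in colon and the 844 higher in small intestine coloured and the line of equal signal drawn.

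The 13 genes with the largest rise in colon were led by Slc6a14 and Sult1a1. Slc6a14, an amino acid transporter, was at 11.55 ± 0.52 in colon and not above background in small intestine, a difference of at least 71.3-fold (adjusted p = 7.53e-08). Sult1a1, a phenol sulfotransferase, rose by 6.60 (SE 0.23), from 6.05 ± 0.42 in small intestine to 12.65 ± 0.20 in colon (adjusted p = 4.13e-08). Wfdc2, a secreted whey acidic protein domain family member, rose by 6.34 (SE 0.21). Sycn, known from pancreatic zymogen granules, rose by 6.15 (SE 0.25), and Hao2, a peroxisomal hydroxyacid oxidase, by 6.02 (SE 0.22). The transglutaminase Tgm3 was at least 39.0-fold higher in colon. St6galnac6, a sialyltransferase, was at least 32.3-fold higher, Lpl, lipoprotein lipase, at least 30.3-fold, and Plet1, an epithelial surface protein, at least 29.2-fold. The cytochrome P450 gene Cyp2d34 was at least 26.8-fold higher. Atp12a, a proton-potassium pump gene, was at 10.57 ± 0.29 in colon and not above background in small intestine. The transcript 1810065E05Rik rose by 5.67 (SE 0.22), and the homeobox gene Hoxa7 by 5.19 (SE 0.25).

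The 13 genes with the largest excess in small intestine were led by Defa22 and Cd74. The alpha-defensin Defa22 stood at 13.57 ± 0.15 in small intestine and 7.80 ± 2.97 in colon (log2 fold change -5.77, SE 1.12, adjusted p = 0.00357). Defa20 stood at 14.67 ± 0.11 and 9.20 ± 3.10 (log2 fold change -5.46, SE 1.17). Alpha-defensin genes are near-identical copies, so the member named by a probe is uncertain. Cd74, the invariant chain of MHC class II, stood at 11.78 ± 0.58 and 6.02 ± 0.88 (log2 fold change -5.75, SE 0.42, adjusted p = 4.6e-06). Olfm4, a glycoprotein of crypt base cells, fell by 5.66 from small intestine to colon (SE 0.67), and Reg1, a secreted C-type lectin, by 5.23 (SE 0.59). Of the brush border enzymes, Enpp7, an alkaline sphingomyelinase, had a log2 fold change of -5.68 (SE 0.52), and Anpep, aminopeptidase N, of -5.58 (SE 0.80). Cyp3a11, a drug-metabolising cytochrome P450, fell by 5.62 (SE 0.47). The transporter genes Slc2a2, which encodes GLUT2, and Slc7a15 fell by 5.24 (SE 0.34) and 5.23 (SE 0.62). The organic anion exporter Abcc2 was at least 36.7-fold higher in small intestine, and the lipase gene Pnliprp2 at least 23.7-fold. Akp3, an intestinal alkaline phosphatase, was not above background in colon and differed widely between the small-intestinal arrays (10.01 ± 2.62, adjusted p = 0.00248). Akp3 was higher in small intestine by at least 4.52 log2, or by at least 5.68 without small-intestinal replicate 2 and 3.76 without small-intestinal replicate 4. Single arrays moved some of these folds by over 1.5 times. The log2 fold change of Defa22 was -6.61, -4.95, -4.91 and -6.65 without colon replicates 1 to 4 in turn. That of Defa20 was -6.28, -4.11 and -6.27 without colon replicates 1, 3 and 4, and that of Anpep was -4.81 and -6.47 without colon replicates 3 and 4. Enpp7 moved to -6.33 without colon replicate 4, and Reg1 to -4.62 without colon replicate 2.

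**Figure D2:**
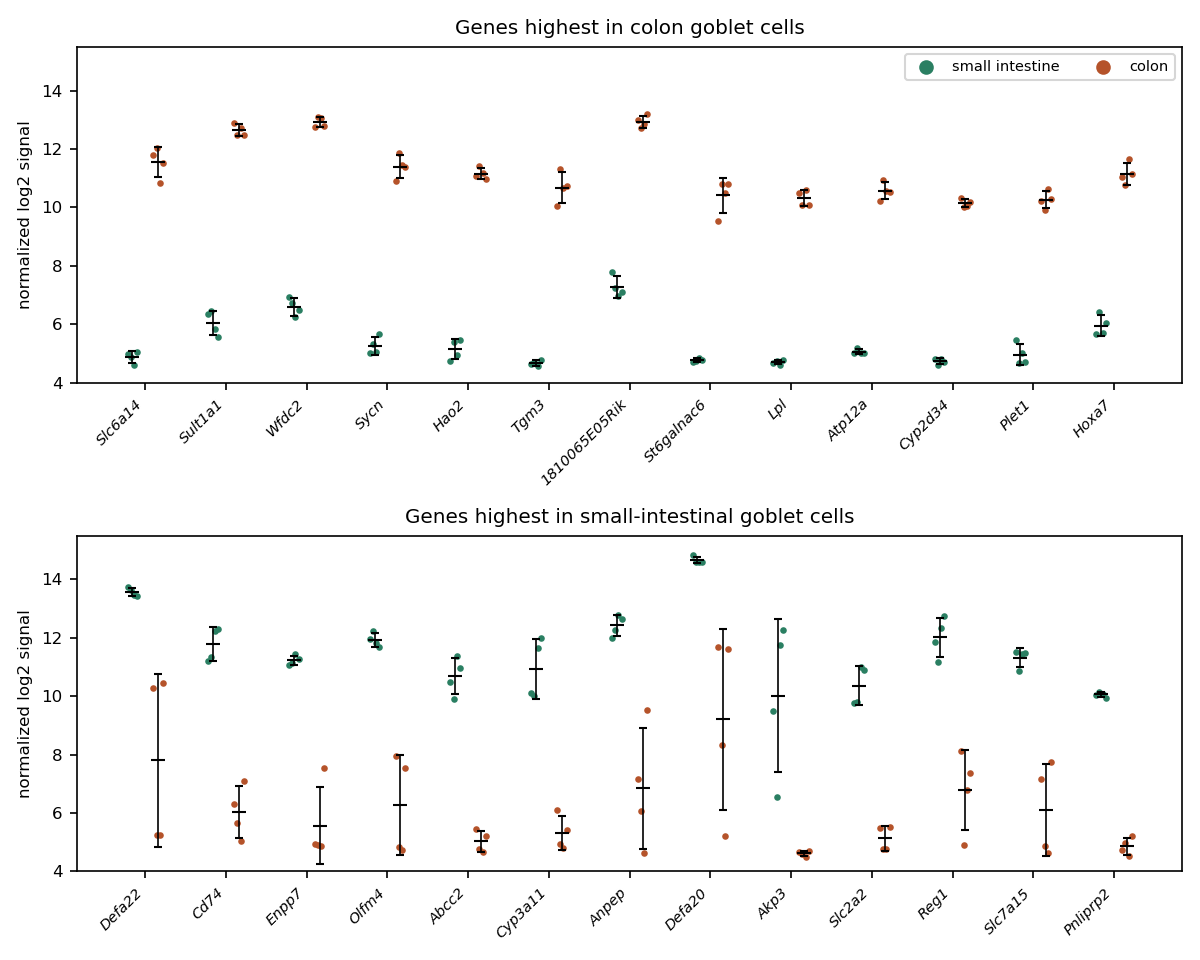
Normalized log2 signal (y) of the 13 genes highest in colon (top) and the 13 highest in small intestine (bottom), 1 point per array, with bars for mean ± SD (n = 4 per segment). The colon values of Defa22, Defa20, Anpep and Olfm4 spread over several log2 units, while those of the genes highest in colon lie close together.

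Genes of the mucus programme were on balance higher in colon. Of 29 tested genes of goblet cell products and regulators, 19 were higher in colon, 0 were higher in small intestine and 10 did not pass (camera, adjusted p = 2.06e-09; adjusted p = 0.132 with an estimated correlation). Adjusted over the list alone, 21 were higher in colon and 1 in small intestine. Best2, a bestrophin channel of colonic goblet cells, was at least 9.27-fold higher in colon, and Retnlb, the antimicrobial resistin-like molecule beta, at least 10.6-fold. The 15 members that also stand in other lists count in both. The median was 0.99 log2. In the same samples, the medians of other cell types' markers were -3.77 for enterocytes, -4.33 for Paneth cells, -0.99 for lymphocytes, -0.81 for enteroendocrine cells, 0.19 for tuft cells and 3.03 for colonocytes.

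Enzymes that build and sulfate mucin O-glycans also shifted towards colon: 24 of 44 were higher in colon, 4 in small intestine and 16 did not pass (camera, adjusted p = 6.92e-06; adjusted p = 0.0453 with an estimated correlation). Adjusted over the list alone, these were 26 and 4. St6galnac6 and Fut2 rose the most. St3gal4, which adds a terminal sialic acid, and Gal3st2, a galactose sulfotransferase, went the other way, by -1.83 (SE 0.24, adjusted p = 0.000228) and -1.45 (SE 0.23, adjusted p = 0.000873). Mucins and trefoil factors as a list did not shift (8 tested, camera, adjusted p = 0.653), with 2 higher in colon and 1 in small intestine, the same numbers adjusted over the list alone. Muc4, a membrane mucin, was higher in colon by 1.65 (SE 0.39), and Itln1, intelectin, was lower by -3.23 (SE 0.58). Genes of folding and stress in the endoplasmic reticulum went both ways, 3 higher in colon and 6 in small intestine of 33 (3 and 7 adjusted over the list alone; camera, adjusted p = 0.0713). Ern2, the stress sensor of mucin-secreting cells, rose in colon by 2.11 (SE 0.26), and Manf, a secreted stress protein, was lower by -0.84 (SE 0.17). That list passed under 7 of 34 alternatives (adjusted p from 0.0154 to 0.215). Without scaling between arrays, Muc4 (adjusted p = 0.0539) and Manf (0.0560) lost their calls.

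Regulators and products of gut position separated the segments. Of 30 tested transcription factors patterned along the gut, 18 were higher in colon, 5 in small intestine and 7 did not pass (camera, adjusted p = 0.000203; adjusted p = 0.0453 with an estimated correlation). Adjusted over the list alone, 19 and 5 passed. Hoxa7 rose as given above, and Hoxa11 was at least 13.5-fold higher in colon. Gata5 and Gata4, factors of the proximal intestine, were lower in colon: Gata5 by -3.29 (SE 0.34, adjusted p = 4.12e-05), and Gata4 at least 5.32-fold. The call was lost under 6 of 34 alternatives (adjusted p from 3.64e-07 to 0.303): with only probes above background on all 8 arrays (0.118), and with the filter re-applied after leaving out any 1 colon array (0.0654 to 0.108) or colon replicates 1 and 4. Of 25 colonocyte markers, 23 were higher in colon, 0 in small intestine and 2 did not pass, the same adjusted over the list alone (camera, adjusted p = 8.97e-17; adjusted p = 0.0325 with an estimated correlation). Their median was 3.03 log2, or 2.72 with the 8 members not above background in small intestine set at their bound. Slc6a14 and Sult1a1 led this list, of which 14 genes also stand in other lists.

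Absorptive enterocyte genes were present in the sorted small-intestinal cells and far lower in colon. Of 38 tested genes of digestion and uptake, 37 were higher in small intestine and 0 in colon, with a median of -3.77 log2 (camera, adjusted p = 9.5e-31; adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, 37 were higher in small intestine and 1 in colon. All 38 were above background on all 4 small-intestinal arrays. In the ileal bile acid list, 4 of 9 were higher in small intestine and 2 in colon, the same adjusted over the list alone (camera, adjusted p = 0.0311; adjusted p = 0.362 with an estimated correlation). Fabp6, the ileal bile acid binding protein, stood at 13.77 ± 0.21 in small intestine and 10.77 ± 0.37 in colon (log2 fold change -3.00, SE 0.22, adjusted p = 4.63e-06). Abcc3, a basolateral exporter, was higher in colon by 1.33 (SE 0.22). The bile acid list lost its call under 9 of 34 alternatives (adjusted p from 0.00393 to 0.423), among them without small-intestinal replicate 1 (0.0554) and without colon replicate 2 (0.0625). With the filter re-applied, it lost its call on leaving out any 1 small-intestinal array (0.226 to 0.423).

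Paneth cell genes were abundant in the small-intestinal samples and uneven among the colon samples. Of 13 tested Paneth cell markers, 11 were higher in small intestine and 1, Nupr1, a stress-responsive regulator, in colon, with a median of -4.33 log2 (camera, adjusted p = 1.7e-06; adjusted p = 0.192 with an estimated correlation). Adjusted over the list alone, 11 and 2 passed. Lyz1, the Paneth cell lysozyme, stood at 13.92 ± 0.08 in small intestine and 9.04 ± 2.57 in colon (log2 fold change -4.88, SE 0.97, adjusted p = 0.00421). Without colon replicates 1, 3 and 4 in turn, the log2 fold change of Lyz1 was -5.64, -3.88 and -5.56. Percents of the small-intestinal mean signal were taken for genes called higher in small intestine and above background on all 4 small-intestinal arrays. These also had at least 1000 units of background-subtracted signal there. The choice thus used the colon values too. For the 10 Paneth cell genes chosen, the median percent in colon was 12.5% on colon array 1 and 13.3% on array 4, but 1.22% on array 2 and 0.185% on array 3. The 32 enterocyte genes that met the same conditions gave 6.45%, 3.87%, 2.46% and 13.7% on colon arrays 1 to 4. Secreted antimicrobial proteins and lectins, a list that shares 9 of its 30 genes with others, went both ways. Of 22 tested, 7 were higher in colon and 8 in small intestine (8 and 9 adjusted over the list alone; camera, adjusted p = 0.653), led by Wfdc2 and Retnlb in colon and by Reg1 and Lyz1 in small intestine. With colon replicates 1 and 4 left out and the filter re-applied, 0.0470 was its adjusted p, towards small intestine.

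**Figure D3:**
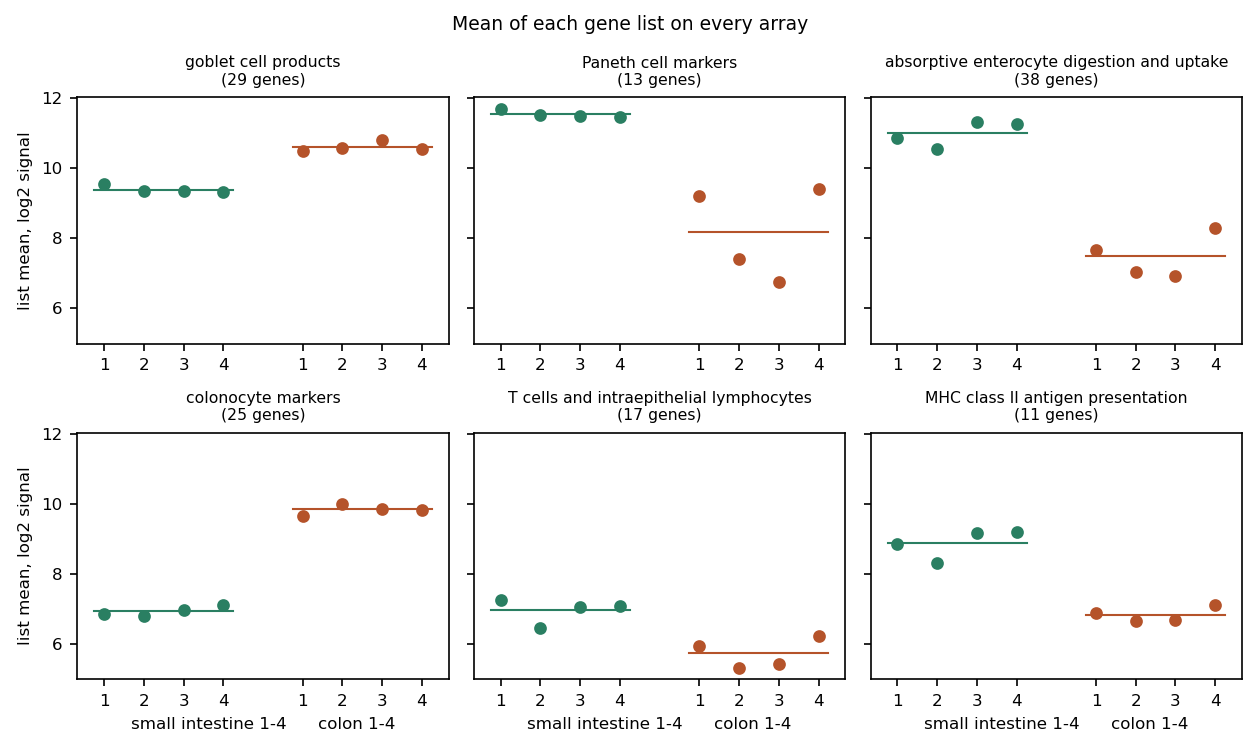
Mean normalized log2 signal (y) of the tested members of 6 gene lists on each of the 4 small-intestinal and 4 colon arrays (x, replicate number), with a line at each segment's mean. Colon arrays 1 and 4 stand at 9.21 and 9.40 for Paneth cell markers against 7.42 and 6.75 on arrays 2 and 3, while colonocyte markers range from 9.66 to 10.01 on the colon arrays.

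Antigen presentation and interferon genes were higher in the small-intestinal cells, alongside lymphocyte markers. Of 11 tested MHC class II genes, 7 were higher in small intestine and 2, the cathepsins Ctse and Ctss, in colon, the same adjusted over the list alone (camera, adjusted p = 0.000203; adjusted p = 0.247 with an estimated correlation). Cd74 fell as given above. H2-Aa, an MHC class II alpha chain, stood at 11.19 ± 0.47 in small intestine and 6.02 ± 0.98 in colon (log2 fold change -5.17, SE 0.43, adjusted p = 9.89e-06). Ctse was higher in colon by 3.42 (SE 0.50), and the call for Ctss was lost under 5 of 34 alternatives, with an adjusted p of up to 0.200. Of 22 MHC class I pathway genes, 12 were higher in small intestine and 1, H2-Q10, in colon, the same adjusted over the list alone (camera, adjusted p = 1e-06; adjusted p = 0.0998 with an estimated correlation). The call for H2-Q10 was lost under 18 of 32 alternatives, 12 of which left out a single array: small-intestinal replicates 2, 3 and 4 and colon replicates 1, 3 and 4, each with and without the filter re-applied (adjusted p from 0.00383 to 0.167). H2-Q2 was lower in colon by -2.38 (SE 0.24), and Nlrc5, the transactivator of MHC class I genes, at least 2.58-fold. Near-identical MHC class I genes can share probe sequence, so single members are uncertain. Of 35 interferon-stimulated genes, 14 were higher in small intestine and 1, Isg20, in colon (17 and 1 adjusted over the list alone; camera, adjusted p = 0.000203; adjusted p = 0.25 with an estimated correlation). Igtp, an interferon-induced GTPase, was lower in colon by -2.21 (SE 0.30), and Isg20, an exonuclease, was at least 5.00-fold higher.

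T cell and intraepithelial lymphocyte markers were also higher in small intestine, 8 of 17 with 0 higher in colon (9 and 0 adjusted over the list alone; camera, adjusted p = 6.92e-06; adjusted p = 0.247 with an estimated correlation). Gzma, granzyme A, stood at 9.97 ± 0.41 in small intestine and 6.53 ± 1.30 in colon (log2 fold change -3.45, SE 0.53, adjusted p = 0.000813). The chemokine gene Ccl5 was lower in colon by -3.08 (SE 0.50, adjusted p = 0.00119). The mean of the list was 5.93 and 6.23 on colon arrays 1 and 4, and 5.31 and 5.43 on arrays 2 and 3. Of 7 tested markers of macrophages, dendritic cells and granulocytes, 3 were higher in small intestine and 2 in colon (4 and 2 adjusted over the list alone; camera, adjusted p = 0.294). This list passed with colon replicates 1 and 4 left out (adjusted p = 0.0499, or 0.00335 with the filter re-applied), towards small intestine. Lyz2, a close paralog of Lyz1, was lower in colon by -2.44 (SE 0.43), and Cd14, the lipopolysaccharide co-receptor, was higher by 1.76 (SE 0.22). Too few markers of B and plasma cells, and of stromal, muscle, endothelial and glial cells, were above background for a list test.

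Of the genes of microbial sensing, Tlr1 and Tlr4 rose the most in colon. Tlr1, a receptor of bacterial lipopeptides, rose by 3.10 (SE 0.25), from 5.24 ± 0.52 in small intestine to 8.34 ± 0.11 in colon (adjusted p = 9.18e-06). Tlr4, the lipopolysaccharide receptor, was not above background in small intestine and at least 4.32-fold higher in colon (adjusted p = 7.69e-06). Tlr2 was above background on 3 colon arrays and 0 small-intestinal arrays, at least 1.75-fold higher in colon, and fell outside the test. Myd88, the adaptor shared by most Toll-like receptors, stood at 8.33 ± 0.40 and 8.53 ± 0.24 (log2 fold change 0.20, SE 0.24, adjusted p = 0.598). Of 26 tested genes of microbial sensing, 7 were higher in colon, 2 in small intestine and 17 did not pass (8 and 5 adjusted over the list alone), and camera did not call the list (adjusted p = 0.132). Ddx58, which encodes the RNA sensor RIG-I, and Ticam1, the adaptor TRIF, were lower in colon, by -1.76 (SE 0.29, adjusted p = 0.00122) and -1.42 (SE 0.31, adjusted p = 0.00717). Ticam1 lost its call with colon replicates 1 and 4 left out (adjusted p = 0.0926), and its other tested probe had the same sign but did not pass. Tlr5 and Tlr9 had no named probe and were not analysed here.

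The muscarinic acetylcholine receptor genes Chrm1, Chrm3 and Chrm4 were at or near background in both segments. Chrm1 was above background on 0 of 8 arrays, Chrm3 on 1 small-intestinal array, and Chrm4 on 1 small-intestinal and 2 colon arrays. None of these was tested. Egfr, the epidermal growth factor receptor, stood at 7.19 ± 0.61 in small intestine and 8.09 ± 0.44 in colon (log2 fold change 0.90, SE 0.32, adjusted p = 0.071). It passed under 5 of 34 alternatives (adjusted p from 0.00367 to 0.297), among them without small-intestinal replicate 1 (0.0191), and 1 of its 4 tested probes had the opposite sign. Of its other tested probes, 2 did not pass either, and the remaining probe did, in a direction not given here. Of 12 tested genes of cholinergic and EGF receptor signalling, 0 were higher in colon and 1, the cholinesterase gene Bche, in small intestine (0 and 0 adjusted over the list alone; camera, adjusted p = 0.459). The call for Bche was lost under 19 of 34 alternatives (adjusted p from 0.0145 to 0.113), among them the omission of any single array but colon replicate 3.

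Several genes of vesicle release were higher in colon, and genes of uptake went both ways. Of 27 exocytosis and granule release genes, 9 were higher in colon and 1 in small intestine, the same adjusted over the list alone (camera, adjusted p = 0.0501). The list passed under 19 of 34 alternatives (adjusted p from 0.0260 to 0.204), among them without small-intestinal replicates 3 (0.0389) and 4 (0.0416) and without colon replicates 1 (0.0423) and 3 (0.0452). Sytl1, a synaptotagmin-like Rab27 effector, rose in colon by 2.62 (SE 0.22, adjusted p = 9.24e-06), and Rab3d, a secretory granule GTPase, by 2.10 (SE 0.25, adjusted p = 0.000143). Stx3, an apical syntaxin, was lower in colon by -1.02 (SE 0.23, adjusted p = 0.00826; 0.0560 with the mean of probes per gene). The other tested probes of Stx3 had the same sign but did not pass. Of 30 endocytosis and transcytosis genes, 3 were higher in colon and 4 in small intestine (3 and 5 adjusted over the list alone; camera, adjusted p = 0.196). Dnm1, dynamin 1, was lower in colon by -3.55 (SE 0.27, adjusted p = 4.71e-06), and Amn, a partner of cubilin in protein uptake, by -2.72 (SE 0.41, adjusted p = 0.000649). Flot2, a flotillin of membrane rafts, was higher in colon by 1.53 (SE 0.40, adjusted p = 0.0178). The call for Flot2 was lost under 6 of 34 alternatives (adjusted p of up to 0.107), among them without small-intestinal replicate 4 (0.0552).

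Transport of ions and fluid also divided the segments. Of 29 tested genes, 15 were higher in colon and 5 in small intestine (16 and 7 adjusted over the list alone; camera, adjusted p = 0.00176; adjusted p = 0.114 with an estimated correlation). Car2, carbonic anhydrase 2, rose from 7.38 ± 1.39 in small intestine to 12.03 ± 0.07 in colon (log2 fold change 4.65, SE 0.54, adjusted p = 0.000115; log2 fold change 4.03 without small-intestinal replicate 2). The anion exchanger gene Slc26a6 was lower in colon by -4.99 (SE 0.35, adjusted p = 3.11e-06), and the aquaporin gene Aqp3 at least 4.87-fold. Aqp3 differed widely between the small-intestinal arrays (7.77 ± 1.43), and its bound was 7.69-fold without small-intestinal replicate 1. Atp12a rose as given above. The list lost its call under 7 of 34 alternatives (adjusted p from 4.41e-05 to 0.217): with only probes above background on all 8 arrays (0.118), without small-intestinal replicates 1 and 2 (0.0588), and with the filter re-applied after leaving out any 1 colon array (0.102 to 0.160) or colon replicates 1 and 4.

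**Figure D4:**
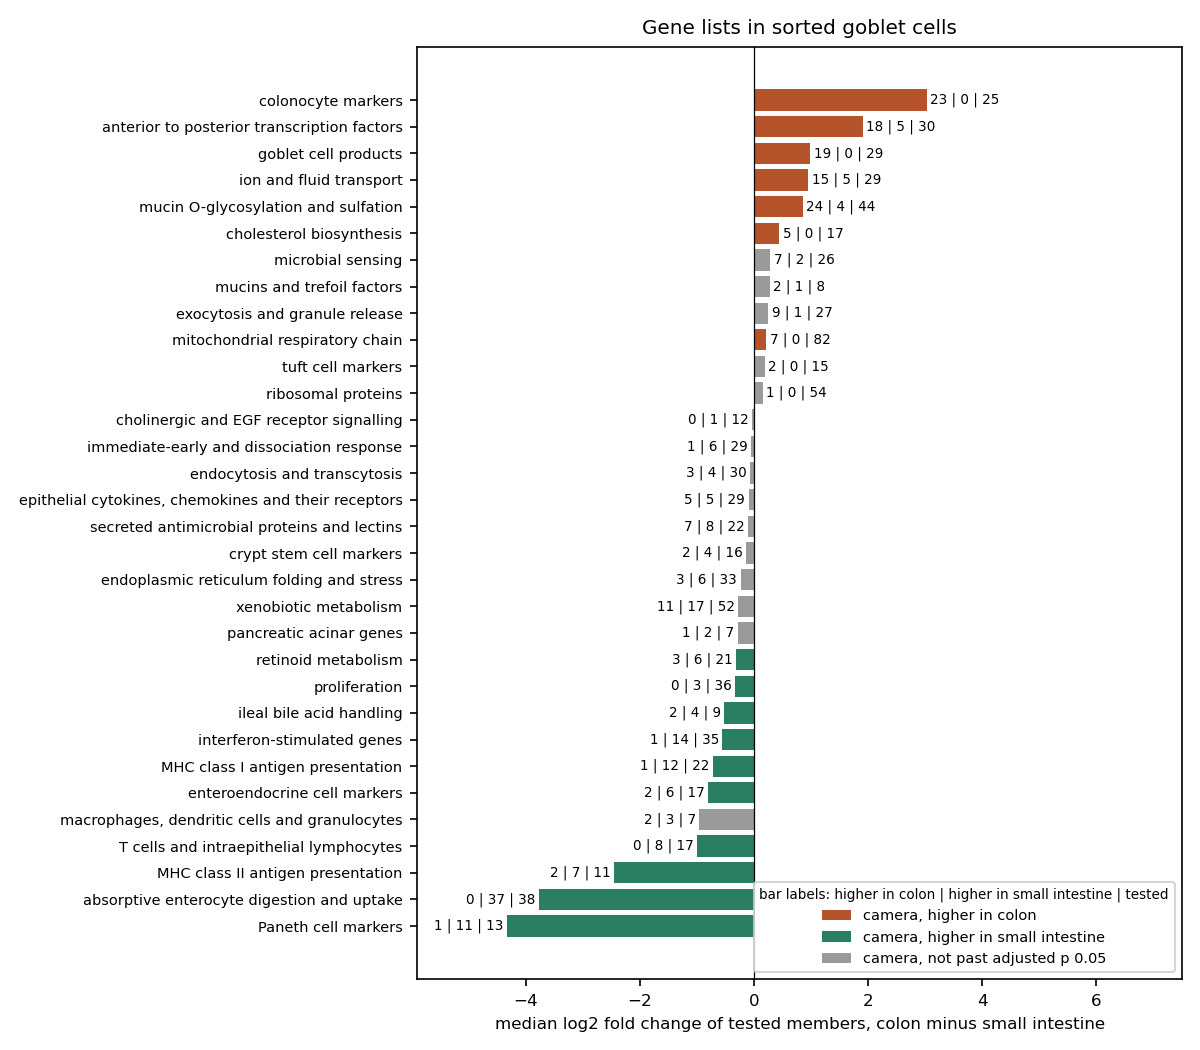
Median log2 fold change of the tested members of 32 gene lists (x, colon minus small intestine), coloured by camera's call at the preset correlation, with the numbers of members higher in colon, higher in small intestine and tested beside each bar. Of the 32 lists, 7 were called higher in colon and 10 higher in small intestine, from a median of 3.03 for colonocyte markers to -4.33 for Paneth cell markers.

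Over all 32 lists tested, 17 passed with camera's preset correlation and 3 with the correlation estimated from each list: colonocyte markers, gut position factors and mucin O-glycosylation. The tuft cell list, which did not pass (adjusted p = 0.977), had a median of 0.19 and a test direction towards small intestine.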

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

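The tests of carry-over and normalization on colon arrays 1 and 4, of the share of goblet cells, of enterocytes, and of B cells and C1q-expressing macrophages taken singly were chosen only after the results were seen, as were the baseline and the bound on single genes in the carry-over test, while the tests of other splits of the arrays and of antigen-presenting cells as a whole were set before.

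Among the 35 ways of splitting the 8 arrays into 4 and 4, only the real split called any probes with limma: 2919, against 0 in each other split, and 1397 genes changed at least 2-fold against a highest of 0. For both counts 1 split of 35 was as large, the smallest share these splits can give, so chance is not excluded. Every other split mixes the segments, which widens the spread within its groups. Counts of 0 there were therefore likely from the start. For gene lists the margin was narrow. The real split called 17 lists and the highest of the other splits 16, again with 1 of 35 as large. The splits with 16 lists still held 3 small-intestinal arrays with 1 colon array, so they part most arrays by segment. Of the splits balanced by segment, small-intestinal replicates 1 and 2 with colon replicates 2 and 3 called the most, 11 lists. The other balanced splits called 0 to 7. The split with 11 lists also parts colon replicates 2 and 3 from 1 and 4, which differ in most Paneth cell transcripts. Leftover separation of the segments thus does not account for all list calls in other splits. Camera with its preset correlation thus called up to 16 lists in splits where limma called 0 probes.

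Single arrays stood far from the other 3 of their segment in 19 of 308 sets of 4 values, or 6.17%, where chance gives about 5%. Small-intestinal replicate 2 held 9 of these and replicate 1 held 5. On replicate 2, the log2 values and the range of the other 3 were 5.19 for Atp12a (5.00 to 5.03), 10.86 for Slc7a15 (11.44 to 11.51), 9.36 for Gzma (10.15 to 10.23) and 7.90 for Cltb (7.06 to 7.19). On the same array, Tnfsf10 was at 6.39 (7.24 to 7.37), Rdh16 at 5.30 (6.03 to 6.12), Krt18 at 11.35 (10.75 to 10.84) and Tff3 at 12.47 (12.61 to 12.64). The enteroendocrine list had a mean of 8.35 there (7.60 to 7.67). On small-intestinal replicate 1, the values were 14.83 for Defa20 (14.61 on each of the others), 9.80 for Cd24a (9.54 to 9.58), 8.99 for Manf (9.31 to 9.33), 8.90 for Rdh7 (9.51 to 9.63) and 12.15 for Clca1 (12.55 to 12.58). On small-intestinal replicate 3, Muc1 was at 5.28 (4.93 to 4.96). In colon, Enpp7 was at 7.54 on replicate 4 (4.86 to 4.92), Hoxa11 at 8.60 (9.28 to 9.38) and Sytl1 at 8.54 (8.79 to 8.80) on replicate 1, and Cdca8 at 7.59 on replicate 3 (6.86 to 6.91).

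Colon arrays 1 and 4 held more of most Paneth cell transcripts than arrays 2 and 3, with medians of 12.5% and 13.3% of the small-intestinal signal against 1.22% and 0.185%, while many enterocyte genes were present on all 4. Normalization between arrays as the cause is argued against, since in the raw signals the log2 ratio of arrays 1 and 4 over 2 and 3 had a median of 2.67 over 10 Paneth cell genes (range -0.55 to 3.49, above 0 for 9, with Clps below). An even carry-over of small-intestinal RNA needs Paneth and enterocyte genes to gain the same percent, but over the mean percent on arrays 2 and 3, array 1 gained 10.7% for Paneth genes and 2.17% for enterocyte genes, a ratio of 4.94 against an upper bound of 2 (permutation test, two-sided, 100000 resamples, p = 4e-05), while on array 4 the ratio was 1.93 (11.7% and 6.04%, permutation p = 0.0768). This baseline was adopted after the ratios without one, 1.94 on array 1 (permutation p = 0.0918) and 0.969 on array 4 (permutation p = 0.915), had met the bounds of 0.5 to 2, and after those over array 3 alone (5.01 and 1.76), as was a further bound of fewer than 3 genes with under 0.25 of the median gain (4 genes on array 1, 2 on array 4), so the case against even carry-over on array 1 rests on choices made after the result. The resamples shuffled genes within 1 array, not samples. Several of the Paneth genes were alpha-defensins, which are near-identical copies, so the genes are not independent and these p-values do not measure a spread between samples. Both gene sets held only genes called higher in small intestine, so colon values entered the choice. On array 4 even carry-over met its bounds, but enterocyte genes low on arrays 2 and 3 reached unlike percents there. These were 26.5% for Apoa1 and 24.1% for Apoa4, against 1.10% for Cyp3a11 and 2.08% for Slc2a2. Even carry-over is therefore not settled for array 4. For array 1 a mixture richer in Paneth cell RNA, or a biological difference between the colon samples, stays open and untested.

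Enterocyte genes were higher in small intestine by a median log2 fold change of -3.77 despite the goblet cell gate, with Anpep at 12.43 ± 0.36. A lower share of goblet cells in those samples would raise the markers of other cell types alike only if these entered in equal proportion. The tuft cell median lay 3.96 log2 units from the enterocyte median (permutation test, 100000 resamples, p = 1e-05, the smallest the resamples can give). The enteroendocrine median lay 2.96 from it (permutation p = 0.00018). The rise was thus unequal, but other cell types need not enter in equal proportion. The resamples also shuffle genes, not samples, and the tuft list means of 5.87 to 6.24 log2 lay near the floor. The test therefore cannot decide on the share of goblet cells. Some values go with a lower share. Goblet cell products had a median of 0.99 and Spdef a log2 fold change of 1.54, both towards colon. Paneth, lymphocyte and enteroendocrine medians of -4.33, -0.99 and -0.81 lay towards small intestine. The colonocyte and tuft cell medians of 3.03 and 0.19, also of cells other than goblet cells, lay towards colon. Tff3, Clca1 and Krt18, however, did not pass, at log2 fold changes of -0.31, 0.33 and 0.33. A part of a lower share in the pattern is thus not excluded. All 38 tested enterocyte genes, of which 3 stand in another list too, were above background on all 4 small-intestinal arrays, so enterocytes passing the gate may contribute. The sort and the segment coincide with the groups, so such cells cannot be told apart from expression of these genes in small-intestinal goblet cells.

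Of 11 MHC class II genes, 7 were higher in small intestine and 2 in colon (camera, adjusted p = 0.000203; adjusted p = 0.247 with an estimated correlation). Of 8 markers of B cells, macrophages and dendritic cells on the array, 2 were higher in small intestine without a filter on dim probes (Tyrobp and Cd79b), which met neither bound set before (at least 4, or fewer than 2), so antigen-presenting cells as a whole stay open. A further bound set before, on the gap between the levels of these markers and of MHC class II genes (6.90 log2), was set aside after it was seen, since levels of different probes cannot be compared. Of the B cell markers, Cd79a, Cd79b and Ms4a1 were above background on at most 1 of 4 small-intestinal arrays. The macrophage markers C1qa, C1qb and C1qc were above background on 0 arrays. None of these probes was above background in colon either, so their silence cannot exclude a small share of such cells. Cd79b was also among the markers higher in small intestine. B cells and C1q-expressing macrophages therefore stay open too. Dendritic cells, for which Itgax was above background on 1 array of each segment, and expression in the epithelium of the small intestine remain open. The CD45 gate is meant to remove dendritic cells. However, Ptprc, which encodes CD45, was above background on all 4 small-intestinal arrays, at 7.24 ± 0.41 against 6.25 ± 0.38 in colon. The gate therefore cannot be taken as complete.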

How the results depend on the processing

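Alternatives that left out 2 arrays together, and the switch from re-applying the filter at each omission to testing the same probes, were chosen only after the data were seen, the switch after larger losses with the filter re-applied. No named gene and no list changed direction where it was called, under any alternative. Of 110 called named genes, 79 kept their call under all of the 34 alternatives of the fit that tested them, and so did 9 of 17 called lists. With array weights, 2672 probes were higher in colon and 2397 lower. Without scaling between arrays, 744 were higher. With small-intestinal replicates 1 and 2 left out, 1930 were higher and 1646 lower. With colon replicates 1 and 4 left out, from as few arrays, 938 were higher and 805 lower. With the filter re-applied as well, these were 657 and 757. Re-applied after single omissions, it gave 1044 higher without colon array 4, and 777 and 798 lower without small-intestinal arrays 3 and 4, from fewer arrays and probes. With only probes above background on all 8 arrays, 847 were lower and 827 genes differed at least 2-fold, from fewer probes tested. Without background correction 673 genes differed at least 2-fold, and with normexp at offset 50 and no detection information 916. The causes of the moves with array weights, between-array scaling and background correction were not tested. With estimated correlations, 3 lists passed, and the cause was not tested. With fry, which compares a list with no other genes, 20 passed: proliferation lost its call (adjusted p = 0.120), and exocytosis (1.62e-05), microbial sensing (0.00032), endocytosis (0.0133) and endoplasmic reticulum genes (0.0295) gained one. With the same probes tested, leaving out 1 array at a time gave 1180 to 2040 probes higher, 967 to 1787 lower, 1241 to 1667 genes at least 2-fold different and 13 to 19 lists. The number of detected probes differed by -89 between segments at detection p below 0.01 (exact permutation test, two-sided, p = 0.914). Deviations from the segment means correlated by 0.07, 0.25, -0.18 and 0.05 for replicate numbers 1 to 4. Samples with unlike numbers were not compared, so whether the numbers pair the samples stays open. With the replicate number as a block, 1410 probes were higher and 1217 lower in colon. Slide as a block was not run. Signal over background limits the folds: only bounds hold for genes above background on no array of a segment, and folds are understated where a segment's level is near 5.28 to 5.61 log2.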

Other observations

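The test of Hox paralog number was set before the result was seen. Hormone genes of enteroendocrine cells separated the segments within the sorted cells. Of 17 tested markers, 6 were higher in small intestine and 2 in colon (8 and 2 adjusted over the list alone; camera, adjusted p = 0.00877; adjusted p = 0.394 with an estimated correlation). The list mean was 8.35 on small-intestinal replicate 2 and 7.60 to 7.67 on the others, and the call was lost with small-intestinal replicates 1 and 2 left out and the filter re-applied (adjusted p = 0.0648). Gip, the glucose-dependent insulinotropic peptide, was lower in colon by -4.71 (SE 0.55, adjusted p = 0.00012), and Ghrl, ghrelin, by -2.41 (SE 0.27). Pyy, peptide YY, was higher in colon by 2.32 (SE 0.35), and Insl5, a peptide of colonic endocrine cells, at least 3.04-fold. Tuft cell markers did not shift as a list: 2 of 15 were higher in colon (1 adjusted over the list alone), led by the taste G protein gene Gnat3 at 1.29 (SE 0.23; adjusted p = 0.0849 without scaling between arrays). The other tested probe of Gnat3 had the same sign but did not pass. Of 16 crypt stem cell markers, 2 were higher in colon and 4 in small intestine (3 and 4 adjusted over the list alone; camera, adjusted p = 0.243). Cell cycle genes shifted slightly towards small intestine (camera, adjusted p = 0.00196; adjusted p = 0.47 with an estimated correlation), with a median of -0.33 log2 and 3 of 36 called (1 adjusted over the list alone). That call was lost without small-intestinal replicates 1 and 2 (adjusted p = 0.200, or 0.147 with the filter re-applied) and with fry (adjusted p = 0.120). Among pancreatic acinar genes, of which 7 were tested, Cela1, an elastase, was higher in colon by 4.29 (SE 0.25), and Rnase1 and Clps, colipase, were lower by -3.18 (SE 0.29) and -2.40 (SE 0.26). With 1 called higher and 2 lower (1 and 3 adjusted over the list alone), that list did not pass (camera, adjusted p = 0.247).

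Cytokine genes went both ways, 5 higher in each segment of 29 (7 and 7 adjusted over the list alone; camera, adjusted p = 0.572). Il1r1, the interleukin 1 receptor, was higher in colon by 3.62 (SE 0.22, adjusted p = 1.12e-06), and Il1rn, the receptor antagonist, stood at 5.38 ± 0.15 in small intestine and 8.68 ± 0.16 in colon (adjusted p = 6.4e-07). Il33, an alarmin, was at least 4.16-fold higher in small intestine, and Tnfsf10, the death ligand TRAIL, at least 3.03-fold. Retinoid metabolism leaned to small intestine, 6 of 21 against 3 (7 and 5 adjusted over the list alone; camera, adjusted p = 0.0495; adjusted p = 0.247 with an estimated correlation), a call lost under 13 of 34 alternatives (adjusted p from 0.0136 to 0.200), among them without small-intestinal replicates 3 (0.0641) and 4 (0.101) and without colon replicates 2 (0.0599) and 3 (0.0605). Rdh7, a retinol dehydrogenase, was lower in colon by -3.49 (SE 0.29), and Adh4, an alcohol dehydrogenase, at least 5.71-fold. Rbp4, the retinol carrier, was higher in colon by 2.01 (SE 0.31). Of 52 xenobiotic metabolism genes, 17 were higher in small intestine and 11 in colon (17 and 13 adjusted over the list alone; camera, adjusted p = 0.0721). That list passed under 8 of 34 alternatives, among them without small-intestinal replicate 2 (0.0199) and without colon replicate 1 (0.0342). Cholesterol synthesis genes leaned to colon, 5 of 17 with 0 lower (7 and 0 adjusted over the list alone; camera, adjusted p = 0.0392; adjusted p = 0.47 with an estimated correlation), among them Msmo1 at 1.14 (SE 0.20; adjusted p = 0.0754 without scaling between arrays). Mitochondrial respiratory chain genes shifted by a median of 0.21 log2, with 7 of 82 higher in colon (3 adjusted over the list alone; camera, adjusted p = 0.0392; adjusted p = 0.25 with an estimated correlation). Each of these 2 calls was lost under 13 of 34 alternatives. Without single arrays, cholesterol synthesis lost its call on omission of small-intestinal replicates 1 (0.0922) and 4 (0.0598) and colon replicates 2 (0.111) and 4 (0.0838). The respiratory chain lost its call on omission of small-intestinal replicates 1 (0.0601), 3 (0.0637) and 4 (0.0564) and colon replicates 2 (0.0899) and 4 (0.0704). Ribosomal protein genes did not shift (1 of 54 higher in colon, 0 adjusted over the list alone; camera, adjusted p = 0.43), nor did immediate-early genes of tissue dissociation (1 higher and 6 lower in colon of 29, 1 and 7 adjusted over the list alone; camera, adjusted p = 0.158). Of the latter, Socs3 was lower in colon by -1.92 (SE 0.33). Among sex-linked genes, too few for a list test, Xist stood at 10.59 ± 0.15 in small intestine and 10.82 ± 0.16 in colon (adjusted p = 0.395) and Uty at 5.69 ± 0.20 and 5.76 ± 0.11 (adjusted p = 0.838), both above background on all 8 arrays.

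Of 21 tested Hox genes, 19 were higher in colon and 0 lower, among them all 9 of the a cluster, all 6 of the b cluster and all 4 of the d cluster, but neither of the 2 tested c cluster genes. A hypothesis that later-numbered paralogs, which mark more posterior positions in the embryo, are higher in colon by more was not borne out: across genes, which are not independent replicates, paralog number and fold change correlated by Spearman's rho of 0.19 (permutation test, 100000 resamples, p = 0.396) and Pearson's r of 0.10 (p = 0.676). With 21 genes, a weak relation cannot be told apart from none.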
